A study of Arabidopsis thaliana with 2 samples.

How the data were processed

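Whole Arabidopsis thaliana seedlings of the Landsberg erecta accession came from seeds kept cold and dark for 2 days and then given 2 h of white light. They grew in darkness at 23 °C for 7 days and were given 1 h of red light or a further 1 h of darkness, per the labels' protocols. The red light had its transmission maximum at 630 nm and a fluence rate of about 10 µmol per square metre and second. Each of the 2 samples pooled 5 seedlings. Total RNA (20 ng per sample) was copied to cDNA, amplified isothermally into DNA, fragmented and biotin-labelled for an Affymetrix array, per the labels' protocols. The labels differ on the sucrose in the medium, so its content is not given here.

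The deposited values are linear probe set intensities, computed with MAS5 version 5 per the submitters' processing notes. The settings of that step are not given in the sources used here. The intensity values ran from 0 to 13528 on the red light array and to 15866 on the dark array. Their mean without the lowest and highest 2% of probe sets was 500.0 on both arrays, so the arrays carry a common scale and no further scaling was applied in the main setting. No detection calls were used. The 27 probe sets for bacterial transcripts served as a measure of background.

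The table held 22810 probe sets, of which 64 were controls. In the probe annotation used here, 13513 probe sets named 1 gene, 503 named several genes, and 8730 non-control probe sets were unlisted and stay unnamed here. The 13513 probe sets gave 13356 genes, and 13286 of these had an entry in a gene table of the TAIR10.1 assembly, which was used for symbols only. No genome build is named with the values, so no coordinates are given. Mitochondrion-encoded genes were taken from the probe annotation's symbols (nad, cox, ccb and the like), as the gene table has no entry for them. Symbols other than the locus name were found for 1535 genes.

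Signals were turned to log2, and the log2 ratio of red light over dark was taken per probe set. A probe set counted as measured when the mean of its log2 signals reached the 40th percentile of the non-control probe sets, a signal of 102. Probe sets that named several genes were left out, and probe sets of the same gene were averaged, which left 7282 measured genes. A gene was called higher or lower at 2-fold. With 1 array per group there were no replicates, so no test, p-value or error across samples exists, and the number of arrays limits the precision. Batch and group cannot be told apart.

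The gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest and 10 smallest ratios among measured genes called under the main setting, median centring, loess, quantile normalization and an added pseudocount. It also took up to 3 measured members with the largest absolute ratio in each list, and 12 regulators and marker genes to be named always. Members beyond these that appear in the text were chosen after their values were seen. Of the fixed lists, 25 were run. Another, of cytosolic ribosomal proteins, matched 0 genes in the annotation and was not run. Because the annotation names few of the best-known genes, 24 further lists were drawn up from its symbols. When these were drawn up, the first rows of the value table, which held a mitochondrial gene, and the control probe sets had been seen, but no further gene's values. Later the cyclophilin gene CYP71 was taken out of the list of cytochrome P450s, after the results had been seen, since only its symbol had put it there.

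For each list with at least 3 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A list outside the central 95% is described as above or below it. This describes these 2 arrays and is not a test of light. In all, 31 lists were placed and 15 lay outside. For lists of unrelated genes chance alone would put about 1.55 outside. Members of a gene family can vary together, and lists share some members, so the 2 numbers are not a test.

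The alternatives were median centring, loess correction (span 0.3), quantile normalization, a pseudocount of 22.1 (the 25th percentile of the signals), no filter, a filter at the 60th percentile, leaving out probe sets that can cross-hybridize, the brightest probe set per gene, and thresholds of 1.5-fold and 3-fold. Centring on the hybridization controls and counting all probe sets were added after the data had been seen. The steps were tested on simulated data for this comparison, with the 7282 genes' own spread of ratios as noise. Of 100 genes changed 2-fold, 56% were called in the right direction, and of 100 changed 4-fold, 95% were. Of the unchanged genes 7.06% were called, with noise that still contained the real differences. Of 200 unshifted lists of 10 genes, 2% fell outside the central 95%, and with a shift of 0.5 on the log2 scale 85% lay above it. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6, scipy 1.17.1 and matplotlib 3.10.9.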

Results

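Gene expression was measured in 7-day-old dark-grown Arabidopsis seedlings after 1 h of red light and in seedlings kept in the dark for the same hour, with 1 array and 5 pooled seedlings in each group. The seeds of both groups had been given 2 h of white light before the dark growth. The median signal over all probe sets was 203 on the red light array and 191 on the dark array. The highest of the 27 background probe sets reached 20.5 on the red light array and 11.5 on the dark array. The ratio of 3' to 5' signal was 6.55 after red light and 8.44 in the dark for actin, 1.60 and 2.05 for GAPDH, and 3.0 and 3.05 for ubiquitin. A second pair of control probe sets gave 40.1 and 35.8 for actin, 2.06 and 2.11 for GAPDH, and 4.59 and 5.36 for ubiquitin, so the order of the arrays for actin depends on the pair. There were no replicates, so differences are described by their size alone.

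The comparison asks which transcripts differ after 1 h of red light. Of 7282 measured genes, 351 were at least 2-fold higher after red light and 178 at least 2-fold lower. AT5G48490, which encodes a lipid transfer protein, was 40.4-fold higher, with signals of 3646 and 90.3. MSRB6, of the methionine sulfoxide reductase B family, was 30.4-fold higher and AT3G56290 was 20.9-fold higher. AT5G57760 was 48.4-fold lower, AT5G04120 36.3-fold lower and AT1G14940 30.7-fold lower. The pseudocount took the log2 ratios of these 3 from -5.60 to -4.59, from -5.18 to -4.34 and from -4.94 to -4.17.

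Further genes among the largest ratios were AT2G27420, a papain-like cysteine protease gene (14.8-fold higher), the chalcone isomerase-like gene CHIL (13.7-fold) and the glycosyltransferase gene UGT76E11 (13.4-fold). AT5G42760 was 9.88-fold higher, AT1G22630 9.57-fold, AT2G34620 9.29-fold and AT3G21380 8.91-fold. Among the lowest ratios were AT5G50335 (12.8-fold lower), AT4G11610 (10.8-fold), AT4G35720 (10.5-fold), AT2G37670 (8.32-fold), AT5G02580 (8.14-fold), AT2G47780 (6.85-fold) and AT1G65500 (6.74-fold). The red light signal of AT5G57760, 20.9, was next to the highest background probe set, so its fold is poorly bounded. With the pseudocount the log2 ratio of UGT76E11 went from 3.75 to 3.09 and that of AT5G50335 from -3.68 to -3.06.

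**Figure D1:**
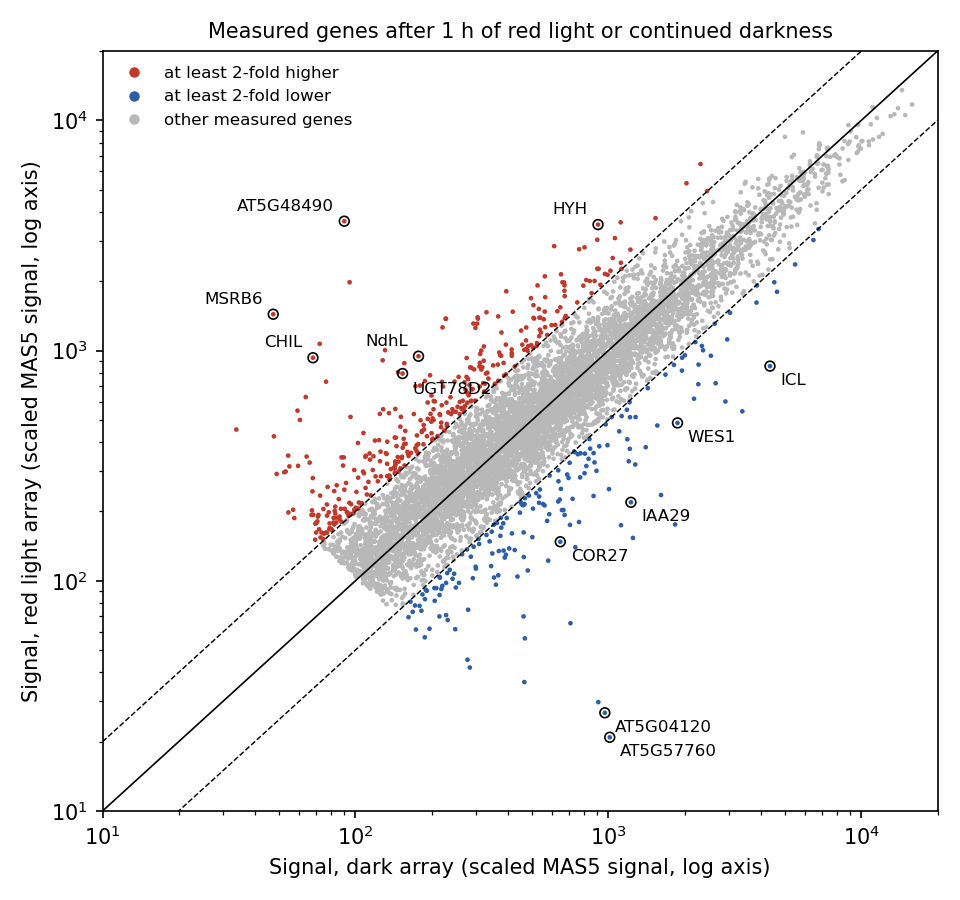
Signal of each measured gene on the red light array against the dark array, both on log axes, with lines at equality and at 2-fold. Red points are the 351 genes at least 2-fold higher after red light and blue points the 178 at least 2-fold lower, and circles mark 12 of the genes named in the text.

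The shares of higher and lower genes depended on the scale. Of the called genes 66.4% were higher in the main setting and 57.5% after quantile normalization. The 18 hybridization controls had a median log2 ratio of -0.30, and 17 were lower on the red light array. Centring on them, an alternative added after seeing the data, moved the median of all genes to 0.30 and gave 705 higher and 91 lower genes, 88.6% higher. Called under the main setting, median centring, loess, quantile normalization and the pseudocount alike were 283 higher and 138 lower genes. The 283 is also the count of higher genes with the pseudocount alone. Centring on the hybridization controls raises every ratio by 0.30, so the 283 had to stay called. Of the 138 lower genes only 91 stayed called with it.

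Regulators of light responses and the clock were among the genes at least 2-fold apart. HYH, a bZIP factor related to HY5, was 3.87-fold higher after red light, with signals of 3525 and 909.8. AFR, an F-box gene of phytochrome A signalling, was 4.06-fold higher, and the clock gene GI was 2.35-fold higher. IAA29 was 5.60-fold lower and COR27, a cold- and light-regulated gene linked to the clock, 4.37-fold lower.

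Of the 29 light-responsive regulators on the fixed list only HYH was measured. Of the 17 genes on the shade-avoidance list AT5G02580 and IAA29 were measured, both lower. Of the 23 genes on the clock list 2 were measured, GI and TIC, and TIC had a log2 ratio of 0.16. A wider list of light signalling and clock genes, drawn up from the annotation's symbols, had 3 of 12 members at least 2-fold higher and 2 at least 2-fold lower. Its median was -0.04, at percentile 37.7 of matched random lists. No probe set named HY5, PHYA, PIL1, CCA1, LHY, TT4, ELIP1, ELIP2, HEMA1, PORA, SPA1 or IAA19 alone, and these 12 genes are not analysed here. The photoreceptor list had no measured member. Of its 18 genes only FHL had a probe set naming it alone, and its signals of 24.2 and 20.0 did not count as measured. The other genes of that list are thus not analysed here.

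Photosynthesis transcripts were higher after red light. In the fixed list of photosystem subunits and carbon fixation 7 of the 34 genes written were measured. All 7 had a ratio above 0, with a median log2 ratio of 0.59 at percentile 100.0 of matched random lists. None reached 2-fold. PSBW, a small photosystem II subunit, was 1.79-fold higher, PSAE-1 1.70-fold, and the Calvin cycle gene SBPASE 1.53-fold. Of the 19 genes on the antenna list 2 were measured. LHCB4.2 was 2.62-fold higher, while LHCB4.1 had a log2 ratio of -0.02, and of 0.16 with loess.

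The wider list of 30 nuclear-encoded photosynthesis and thylakoid genes, which includes those 7, had a median of 0.58 at percentile 100, with 27 members above 0 and 7 at least 2-fold higher. NdhL, NdhS and NdhN, subunits of the chloroplast NADH dehydrogenase-like complex, were 5.32-fold, 3.22-fold and 2.39-fold higher. LHCB4.3 was 2.70-fold higher and the thylakoid calcium sensor gene CaS 2.66-fold higher.

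Plastid-encoded genes were higher too. Of 68 measured plastid genes 63 had a ratio above 0, and their median was 0.46. The 33 photosystem, cytochrome, ATP synthase and Rubisco genes had a median of 0.61 at percentile 100, led by rbcL (2.57-fold higher), psbT (2.46-fold) and atpI (2.03-fold). The 9 measured genes of the NDH complex had a median of 0.46 at percentile 99.9, with ndhJ 1.72-fold, ndhA 1.69-fold and ndhH 1.65-fold higher and none past 2-fold. With centring on the hybridization controls ndhJ, ndhA and ndhH were past 2-fold. The 19 RNA polymerase and ribosomal protein genes had a median of 0.36 at percentile 100, with rps18 2.92-fold, rps14 2.34-fold and rps15 1.64-fold higher. Beside these, the 10 measured mitochondrion-encoded genes had a median of 0.39 at percentile 99.1. The ratio of atpI was under 2-fold with loess, quantile normalization and the pseudocount.

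**Figure D2:**
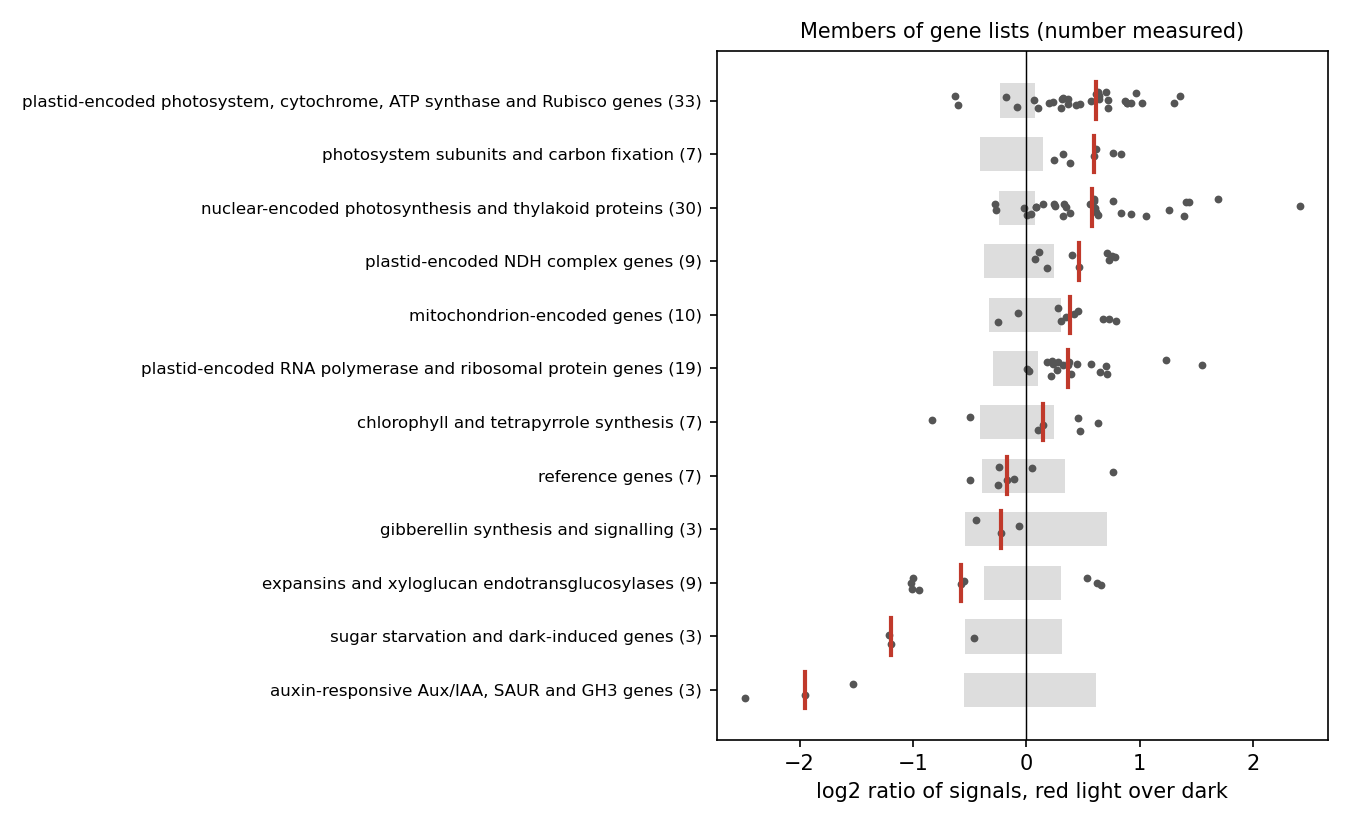
Log2 ratio of red light over dark for the measured members of gene lists, 1 point per gene, with the list median as a red bar and the central 95% of medians of matched random lists as a grey band. The photosynthesis and plastid lists lie above the band, with medians from 0.36 to 0.61. The mitochondrion-encoded genes also lie above it, with a median of 0.39. The expansin, starvation and auxin lists lie below the band, with medians of -0.58, -1.19 and -1.95.

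Of the 19 genes on the flavonoid list 2 were measured, too few to place against random lists. CHIL was 13.7-fold higher, with signals of 930.5 and 67.9, and UGT78D2, a flavonoid glucosyltransferase gene, was 5.18-fold higher. DFR, which encodes dihydroflavonol reductase, had signals of 55.4 after red light and 0.3 in the dark and did not count as measured. In the carotenoid list, the lycopene cyclase gene LYC had a log2 ratio of 0.29.

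The few measured chlorophyll and tetrapyrrole genes did not all move together. Of 27 genes on the fixed list 7 were measured, 5 above 0 and 2 below. Their median was 0.14 at percentile 92.8, inside the central 95%, and none was 2-fold apart. With no filter 8 members had a median of 0.23 at percentile 97.2, just inside. PORB, a protochlorophyllide oxidoreductase gene, was 1.78-fold lower, HEME1 1.55-fold higher and GSA1 1.41-fold lower. In the wider list of 11 tetrapyrrole enzymes the median was 0.10 at percentile 85.7, with hemb2 at a log2 ratio of -2.72 and hemf2 1.91-fold lower. The ratio of hemf2 passed 2-fold with loess and quantile normalization.

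Of the 35 auxin-responsive genes on the fixed list, 3 were measured. All were at least 2-fold lower after red light: IAA29 by 5.60-fold, WES1 by 3.87-fold and GH3.3 by 2.89-fold. WES1 and GH3.3 encode enzymes that join auxin to amino acids. The list's median of -1.95 lay below all 10000 random lists, at percentile 0. The wider list of 6 auxin genes includes these 3, so it is not separate evidence. Of the 6, 5 lay below 0 and 4 were at least 2-fold lower, with a median of -1.59 at percentile 0. IAA20 was 3.15-fold lower and GH3.17 1.41-fold lower, while IAA18 had a log2 ratio of 0.48. With no filter on dim probe sets the median of the wider list was -0.22, inside the central 95%.

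Cell wall loosening genes were mostly lower. Of 27 expansin and xyloglucan endotransglucosylase genes on the fixed list 9 were measured. Their median was -0.58 at percentile 0.06, with 6 below 0 and 3 above. XTH19 was 2.03-fold lower, XTH18 2.02-fold and EXPA8 2.00-fold, all at the edge of the threshold: XTH19 was under it with loess, XTH18 with loess and quantile normalization, and EXPA8 with the pseudocount. Centring on the hybridization controls put all 3 under it. XTH16 (log2 ratio 0.66) and EXPB3 (0.62) lay on the other side. The 11 measured expansins of the wider list include the measured expansins of the fixed list. Their median was -0.58 at percentile 0.02, and EXPA4 is the median gene of both lists. EXPA9 led at 4.19-fold lower, with EXLA3 1.94-fold lower. The wider list lay inside the central 95% with the stricter filter. The ratio of EXLA3 passed 2-fold with loess and quantile normalization. The 6 xyloglucan endotransglucosylases of the wider list had a median of -0.26 at percentile 15.6, and XTH32 was 2.51-fold higher.

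The few measured genes known from sugar starvation and darkness were lower. Of 18 genes on the list as written 3 were measured, with a median of -1.19 at percentile 0.005. MCCA and IVD, which act in leucine breakdown, were 2.31-fold and 2.29-fold lower, and AKINBETA1, a subunit of the SnRK1 kinase, had a log2 ratio of -0.46. MCCA and IVD were under 2-fold with centring on the hybridization controls, where the list's median was -0.89. ICL, the isocitrate lyase gene of the glyoxylate cycle in germinating seedlings, was 5.09-fold lower, with signals of 855.6 and 4352. It was the measured member of the list of seed storage, oil body and late embryo genes, in which PAP85 had signals of 82.8 and 112.

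Gibberellin genes had a median of -0.22 at percentile 20.6 over GID1B (-0.45), GID1A (-0.22) and GID1C (-0.07), the gibberellin receptors. Reference genes had a median of -0.17 at percentile 25.1 over 7 members, with AT2G32170 at 0.76, AT4G26410 at -0.50 and PEX4 at -0.25. Both medians turned positive with centring on the hybridization controls, at 0.08 and 0.13. Single measured members gave log2 ratios of -0.51 for EIN3 of ethylene signalling, 0.72 for RR16 among cytokinin response regulators, -0.66 for the heat shock gene AT1G53540 and -0.33 for the root marker PYK10. The root hair expansins EXPA7 (signals of 8.8 and 26.4) and EXPA18 (13.5 and 52.3) were lower on the red light array. There both lay under the highest background probe set, and neither counted as measured. WRKY53 (-0.58) and STZ (0.27) stood for touch and wounding, and LEA4-5 (-0.71) and COR47 (-0.29) for cold, drought and abscisic acid. The lists of brassinosteroid and of cell cycle genes had no member with a probe set naming it alone. The oxidative stress list and the shoot apex and epidermis list had 1 such member each, which did not count as measured. Of the 25 fixed lists, 18 had fewer than 3 measured members and were not placed against random lists.

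For 37 pairs of measured probe sets naming the same gene, the log2 ratios differed by a median of 0.27, and 1 pair differed by more than 1. The SD of log2 ratios among genes was 0.70 in the dimmest 1457 measured genes and 0.45 in the brightest 1456. Red light and differences between the pooled samples cannot be told apart in this design.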

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

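All 5 tests in this part were chosen after the results were seen. The values they use, those of the mitochondrial genes, the ribosomal RNA controls and the seed loci, had been looked at before the thresholds were set, so these tests can at most speak against an explanation and cannot bear it out.

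Among probe sets that the annotation leaves unnamed here, 344 of 6048 measured ones (5.69%) were at least 2-fold higher after red light and 182 (3.01%) at least 2-fold lower. The comparison of named genes, of which 4.82% were higher and 2.44% lower, does not use them. Probe set 258321_at was 84.8-fold higher, with signals of 3894 and 45.9. Probe set 249769_at was 35.9-fold higher, with signals of 690 and 19.2, the second close to background, so its fold is poorly bounded. In the other direction 255805_at had signals of 11.6 and 941, the first under the highest background probe set, so no fold is given for it, and 255516_at was 12.6-fold lower.

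Plastid-encoded transcripts were higher after red light, in 63 of 68 genes. The signal-dependent trend of the ratios is argued against by its direction: the brightest 1456 measured genes had a median log2 ratio of -0.10. With the stricter filter 64 of the 68 plastid genes remained, so most are bright. Loess could therefore hardly lower their median, which was 0.50 after it, and that value is not separate evidence. Carry-over of RNA without a poly(A) tail, ribosomal RNA included, stays open, as the 2 ribosomal RNA controls disagree: the 25S control had a log2 ratio of -0.10, and the dim 5S control one of 0.61, with signals of 84.5 and 55.2. A larger share of organellar RNA in the amplified red light sample stays open too: mitochondrial genes had a median of 0.39, close to the plastid median of 0.46, though with no filter they lay at percentile 96.6, inside the central 95%. That share could not account for the nuclear-encoded photosynthesis genes, and an effect of red light on plastid transcripts was not tested.

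Seed and late-embryo transcripts were lower after red light, first noticed in ICL, AtLEA4-1 and LEA18. Of these, ICL is a glyoxylate cycle gene of germinating seedlings rather than a late-embryo gene. A longer list of seed loci was drawn up before their values were seen, and trimmed afterwards of those already known, which left 43. Its 11 measured members had a median log2 ratio of -0.59 at percentile 0.01, from 2.49-fold lower for AT3G17520 to a log2 ratio of 0.35 for AT2G28490, with M17, the brightest, at 0.16. The signal-dependent trend is argued against by its direction here too: the dimmest 1457 measured genes had a median log2 ratio of 0.11. Loess could thus hardly raise the median of these mostly dim loci, which was -0.70 after it. With the stricter filter 4 loci had a median of -0.30, inside the central 95%. Seedlings of the dark sample less advanced out of the seed stage, or seeds that did not germinate, may account for the lower values and cannot be told apart from an effect of red light, since each group is a single pool.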

How the results depend on the processing

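No paired analysis was possible because each group has 1 sample. Centring on the hybridization controls and counting all probe sets were chosen after seeing the data. Against 351 higher and 178 lower genes, the counts were 1822 and 1278 with no filter, 172 and 89 with the stricter filter, 925 and 652 at 1.5-fold, 93 and 55 at 3-fold, 712 and 367 over all probe sets, and 705 and 91 with hybridization control centring. The 1.5-fold and 3-fold counts follow from the threshold, and the hybridization control counts from a shift of 0.30. The higher and lower shares of genes were 4.82% and 2.44% in the main setting, 13.6% and 9.57% with no filter, 3.72% and 1.93% with the stricter filter, and 5.22% and 2.69% over all probe sets, and their cause was not tested. The other alternatives gave 283 to 353 higher and 143 to 214 lower genes. No named gene that was at least 2-fold apart in the main setting turned its sign, nor did the median of any list that lay outside the central 95% there. Others near 0 did: LHCB4.1 went from -0.02 to 0.16 with loess and 0.22 with quantile normalization, PEX4 from -0.25 to 0.05 with hybridization control centring, and the median of AGAMOUS-like factors from -0.03 to 0.82 with no filter. That no named gene past 2-fold turned was largely fixed beforehand. A pseudocount cannot turn a sign, a shift of 0.30 is too small to, and filters leave the ratio of a gene with a single probe set unchanged. Of 31 lists, the glycosyltransferase list came inside the central 95% and the SWEET list moved above it with loess and with quantile normalization, and the SWEET list did so with the pseudocount. With no filter 3 lists came inside and 3 moved out, and with the stricter filter 3 came inside, 1 moved out and the gibberellin list had too few members for a value. The cause was not tested. Leaving out cross-hybridizing probe sets and taking the brightest probe set changed no list's side, and the 2 centrings cannot, since they shift every gene alike. Of 119 named genes, loess took 5 under the 2-fold threshold and 2 past it, quantile normalization 4 and 2, the pseudocount 4 and 0, and hybridization control centring 10 and 15. With the stricter filter 75 of them had a value. Low signal limits the folds: the dimmest 1457 measured genes held 110 of the higher and 52 of the lower genes.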

Other observations

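The lists in this part were drawn up from the annotation's symbols, after the fixed lists. The test of leucine breakdown was written before the values of its loci were seen, but its pathway was picked after MCCA and IVD had been seen.

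Of 23 measured UDP-glycosyltransferases 13 had a ratio above 0 and 10 below, 5 were at least 2-fold higher and none 2-fold lower, with a median log2 ratio of 0.30 at percentile 98.9, inside the central 95% with loess and quantile normalization. UGT78D1 was 4.21-fold higher beside UGT78D2 and UGT76E11. Of 13 beta-glucosidases 3 were at least 2-fold higher, BGLU40 (3.18-fold), BGLU19 (2.44-fold) and BGLU47 (2.11-fold), with a median of 0.44 at percentile 99.7, inside with no filter and with the stricter filter. BGLU47 was under 2-fold with loess, quantile normalization and the pseudocount. SWEET2 was 4.32-fold and SWEET17 2.97-fold higher, and SWEET1 1.66-fold, in a list of 6 sugar transporters with a median of 0.48 at percentile 97.4, just inside. GSTU18 was 3.12-fold higher among 9 glutathione S-transferases, with GSTU26 1.55-fold and GSTU27 at a log2 ratio of 0.58, and a median of 0.22 at percentile 91.9.

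The lists of cold and dehydration genes, stress-signalling regulators and tubulins lay below the central 95%. Of 9 cold and dehydration genes 7 lay below 0, with a median of -0.71 at percentile 0.01, and COR27, XERICO and AtLEA4-1 were 4.37-fold, 2.24-fold and 2.16-fold lower. XERICO and AtLEA4-1 were under 2-fold with centring on the hybridization controls. AtLEA4-1 and LEA18 (log2 ratio -0.85) are also late-embryo genes, and separately listed seed loci were lower too, so the list does not stand for cold and dehydration alone. With the stricter filter it lay inside the central 95%. Of 18 stress-signalling regulators 15 lay below 0, with a median of -0.35 at percentile 0.14, led by WRKY22 (4.03-fold lower), ATL8 (log2 ratio -1.26) and WRKY47 (2.25-fold). ATL8 and WRKY47 were under 2-fold with centring on the hybridization controls, at log2 ratios of -0.96 and -0.87. With no filter the list lay inside the central 95%. Of 7 tubulins 6 lay below 0 and none was 2-fold apart, with a median of -0.63 at percentile 0.09, TUB6 1.91-fold, TUB5 1.67-fold and TUA6 1.56-fold lower and TUA1 at a log2 ratio of 0.56.

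The remaining lists lay inside the central 95%. All 10 autophagy genes had ratios below 0, but their median of -0.18 was at percentile 22.1, with ATG3 at -0.47, ATG8C at -0.30 and APG8A at -0.26, and with centring on the hybridization controls it was 0.12, with 9 of the 10 above 0. The medians were -0.19 for 4 GH9 cellulases (GH9B8 2.29-fold lower, GH9B13 -0.52, GH9C2 0.43), -0.02 for 13 TRICHOME BIREFRINGENCE-LIKE genes (TBL37 0.80, TBL28 0.60, TBL30 0.47) and 0.08 for 7 cytochrome P450s (CYP71B23 -0.40, CYP71B28 0.34, CYP71B29 0.30). They were -0.13 for 14 serine carboxypeptidase-like genes (scpl31 3.42-fold lower, scpl46 2.68-fold higher, scpl35 -0.46) and -0.09 for 22 ubiquitin proteases and conjugating enzymes (UBC18 0.97, UBP19 -0.88, UBP21 0.86). AGAMOUS-like factors had a median of -0.03 over 6 genes (AGL87 0.95, AGL30 -0.76, AGL16 -0.21), and 17 annotated pseudogenes one of 0.29 at percentile 96.7, with AT1G35612 2.07-fold higher, AT5G35880 at 0.76 and AT3G17110 at 0.71. AT1G35612 was under 2-fold with loess, quantile normalization and the pseudocount. With no filter the AGAMOUS-like and pseudogene lists lay outside the central 95%.

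Since MCCA and IVD were both lower, genes of mitochondrial branched-chain amino acid breakdown may be lower together. The test asked whether the other loci of the pathway, 12 by general knowledge, lay below 2.5% of matched random lists, and a median of 0 or above would have spoken against it. The 8 measured loci had a median log2 ratio of -0.43 at percentile 0.66, with 6 below 0. With centring on the hybridization controls the median was -0.13. The percentile stayed the same, which was fixed beforehand because that centring shifts every gene alike. MCCB, the partner subunit of MCCA, was 2.14-fold lower, ETFQO 1.61-fold and ALDH6B2 1.52-fold, while AT2G26800 (0.12) and ETFBETA (0.06) lay above 0. The value speaks for the hypothesis in these 2 arrays and leaves open whether light or the sample set it apart.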
